A study of Arabidopsis thaliana with 6 samples.

How the data were processed

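RNA-seq was made from total RNA of whole seedlings, 3 libraries per nitrogen source, with the Illumina TruSeq RNA kit and 1 ug of RNA, per the labels' protocols. Seedlings grew for 12 days at 22 °C with 16 h of light and 8 h of dark after 2 days of cold, per the labels' protocols. The deposited table gives RPKM values scaled by the authors with the TMM method, per the file's name, for 33602 genes in 6 libraries. TAIR10 and SAMtools are named in the submitters' processing notes; the aligner, the read counter, the annotation version and the read filters are not given in the sources used here. The deposited table also gives each gene's length in kilobases and a fraction per gene that by its name is the largest share of reads mapping to several places; it is above 0 for 2653 genes.

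Tested on the values, RPKM times gene length took the steps of whole reads with 0.5 read added to each gene. Whole reads, within 0.05 read, came out for 100% of genes without multiply mapped reads, for 49.1% to 55.4% of genes with them, and for 96.0% to 96.5% of all genes. This gave library totals of 51409315, 49520237 and 51390243 reads for ammonium nitrate replicates 1, 2 and 3 and 59607085, 49688724 and 63424574 for glutamate replicates 1, 2 and 3. In a gene of 1 kb, 1 read was worth 0.0152 to 0.0211 RPKM and a count of 0 allowed up to 0.0455 to 0.0633 RPKM, taken as 3 reads per library. Floors cover counting error only. More genes had 2 reads than 1 (649 against 213 in ammonium nitrate replicate 1), and more had 4 than 3 (288 against 129), so reads were not independent molecules. Mates of a pair counted as separate reads would give this pattern; the libraries would then hold fewer fragments than reads, and the limits that a count of 0 allows would be higher. Whether mates were counted separately is not given in the sources used here. The implied TMM factors were 0.957 to 0.968 on ammonium nitrate and 1.03 to 1.05 on glutamate. The 10 most abundant genes took 5.37% ± 0.101 of reads on ammonium nitrate and 3.49% ± 0.0495 on glutamate (SD, n = 3).

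Groups and replicate numbers came from the labels. Replicates differed by more than counting noise, with a chi-square per degree of freedom of 10.1 to 14.9, and none was a copy of another. Genes with a mean of at least 1 RPKM over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with an intensity trend, two-sided, and Benjamini-Hochberg adjustment at 0.05. A 2-fold change meant an absolute log2 fold change of at least 1. Folds given without a log2 scale are ratios of mean RPKM. No fold is given for a gene whose group had 0 reads. Genes named were, by a rule set before the data were examined, the 10 largest rises and 10 largest falls among passing genes whose groups did not overlap and whose higher mean was at least 5 RPKM, up to 4 members per list with the smallest p, and 18 genes of nitrogen and amino acid metabolism. Other genes are said to be named after their values were seen. Genes of the organelle genomes were kept in the gene tests and are given only as summed shares of reads.

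The 29 lists set before the data were examined held 530 genes and covered nitrate transport, nitrate assimilation, ammonium transport, glutamate and GABA metabolism, glutamate receptor-like channels, amino acid transport, senescence, autophagy, photosynthesis, flavonoids, glucosinolates, sulfur, phosphate and iron deficiency, salicylic acid and jasmonate defence, wounding, abscisic acid, hypoxia, cytokinin, auxin, root hair, endodermis, root tip, suberin, cell cycle, starch, oxidative stress and the clock. A further 5 lists were taken by product name (ribosomal proteins, expansins, aquaporins, class III peroxidases and heat shock proteins). The 33 lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Gene names and product names came from a TAIR10.1 annotation, which matched 32835 of the 33602 identifiers (97.7%); since it is a later release than the authors' build, no coordinates are given.

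The test was run on simulated data, built from the mean levels of the ammonium nitrate libraries. All genes were given the same dispersion, 0.00294, the median over the better covered genes of those libraries. The spread of single genes and that of the glutamate libraries were not used. The shares below thus do not hold for genes of larger spread. In 40 simulations of glutamate against ammonium nitrate with 200 of 19628 tested genes changed, the test recovered 59.2% of genes changed 1.25-fold, 97.1% at 1.5-fold, 99.3% at 2-fold and 100% at 4-fold. Calls of unchanged genes were 9.45% of all calls on average and 5.65% to 16.2% in single simulations, above the nominal 5%. Of unchanged genes 4.92% had p under 0.05, and 0.149% had p under 0.001, above the nominal share. A further 10 simulations took the number of changed genes, 14390, and their folds from the calls in the real data. In these 1.49% of calls were false. They are no independent check of the real calls. Simulated 2-fold changes had a median log2 change of 0.90, which shows the shrinkage by the pseudocount. In 31 simulated lists camera called the list shifted 2-fold and 0 of 30 unchanged lists. The simulated genes were drawn independently of each other, so this does not show how camera treats lists of correlated genes.

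Alternatives set before the data were examined were pseudocounts of 0.1 and 5 RPKM, no filter and a filter at 5 RPKM, median-of-ratios and equal-total scaling, robust and untrended limma, the replicate number as a block, a test against a 1.5-fold change, an estimated correlation and each library left out. Count models planned for whole reads were not run, since the deposited unit is RPKM. Limma voom on the recovered reads and the removal of genes with multiply mapped reads were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for preparation and plots.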

Results

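RNA from whole Arabidopsis thaliana seedlings of the Columbia ecotype was sequenced after 12 days of growth on agar plates that differed in the nitrogen source. The plates held half-strength Murashige and Skoog salts without nitrogen and 0.5% sucrose, to which either ammonium nitrate or the amino acid glutamate was added at 5 mM. Each group had 3 libraries. The libraries held 49520237 to 63424574 reads assigned to genes, as recovered from the deposited values, which may count both mates of a fragment. Levels are in RPKM, reads scaled to gene length and library size, and are given below as mean ± SD over n = 3 libraries. Fold changes on the log2 scale are those of log2(RPKM + 1), which understates the change of genes with low values, and adjusted p-values are from limma's moderated test with Benjamini-Hochberg adjustment over 20032 genes.

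The comparison asked which genes respond to glutamate as the nitrogen source. Seedlings on glutamate had far lower levels of the nitrate reductases NIA1 and NIA2 and of nitrite reductase NIR1, and far higher levels of the high-affinity nitrate transporters NRT2.1 and NRT2.5, of cytosolic glutamine synthetase genes and of the amino acid transporter LHT1. Genes of salicylic acid-linked defence, headed by PR1, rose together. Of the 37 listed nuclear genes of photosynthesis, 27 fell and 7 rose. In all, 14390 of the 20032 tested genes (71.8%) changed, 7013 higher and 7377 lower on glutamate. Of these, 1908 were at least 2-fold higher and 1110 at least 2-fold lower on the log2(RPKM + 1) scale, a total of 3018. With equal totals per library the larger direction among all changed genes turned, with 8452 higher and 5989 lower (58.5% higher, against 48.7%), and 2177 genes were at least 2-fold higher and 834 lower. The values of the 2 groups did not overlap for 15252 genes, or 76.1% of those tested, where chance gives 10%. With a pseudocount of 5 RPKM the 2-fold total was 1632, and a direct test against a 1.5-fold change called 2304 genes higher and 1799 lower. The first principal component held 91.9% of the variance. The glutamate plates supplied 5 mM nitrogen and the ammonium nitrate plates 10 mM, so the nitrogen source, its amount and the absence of nitrate and ammonium were not separated. The labels do not say that the libraries came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

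On the log2(RPKM + 1) scale BT2 and NIA1, both induced by nitrate, had the largest falls among the genes past the thresholds of level and overlap. BT2 (AT3G48360), which encodes a BTB and TAZ domain protein, fell from 349 ± 18.3 to 1.54 ± 0.315 RPKM, with a log2 fold change of -7.11 ± 0.09 (SE, adjusted p = 9.2e-09). NIA1 (AT1G77760) fell from 164 ± 12.9 to 1.17 ± 0.20 RPKM, or 140-fold. BT1 (AT5G63160), a relative of BT2, fell from 122 ± 14.1 to 3.27 ± 0.589 RPKM. NIA2 (AT1G37130) fell from 540 ± 11.6 to 62.7 ± 5.05 RPKM, and NIR1 (AT2G15620) from 128 ± 9.90 to 11.2 ± 2.59 RPKM. Of the 26 tested genes of nitrate assimilation and the primary nitrate response, 23 fell, 1 rose and 2 did not pass, with a median log2 fold change of -1.69. The exception that rose was NLP7 (AT4G24020), a transcription factor of nitrate signalling, from 23.6 to 28.9 RPKM, named after its values were seen. The list was lower than other genes by limma's camera test with a preset correlation between genes of 0.01 (adjusted p = 2.28e-08; adjusted p = 0.515 with an estimated correlation).

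**Figure D1:**
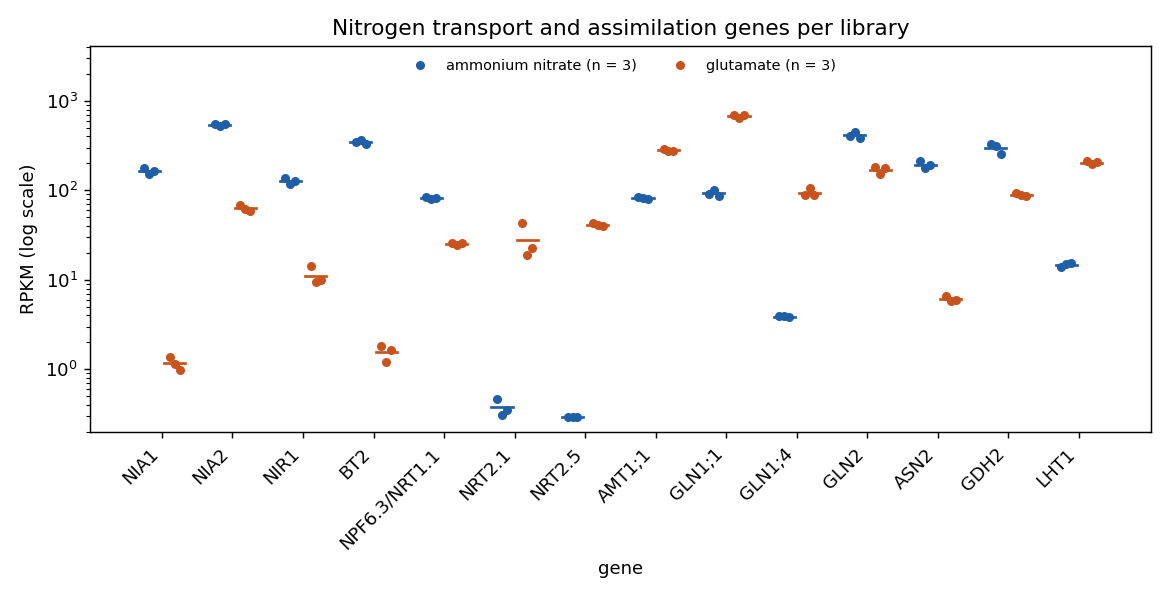
RPKM of 14 genes of nitrogen transport and assimilation, on a log axis, in each library of ammonium nitrate (blue, n = 3) and glutamate (orange, n = 3) seedlings; short lines are group means. NIA1 lies at 164 RPKM on ammonium nitrate and 1.17 RPKM on glutamate, and LHT1 at 14.7 and 205 RPKM.

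The nitrate transporter genes went both ways, with 8 of the 15 tested members higher and 6 lower. NRT2.5 (AT1G12940), a high-affinity transporter of nitrogen-starved plants, rose from 0.292 ± 0.00134 to 41.5 ± 1.21 RPKM, a log2 fold change of 5.04 ± 0.06 (SE, adjusted p = 8.2e-09). NRT2.1 (AT1G08090) rose from 0.374 ± 0.0809 to 28.1 ± 12.8 RPKM, and NPF7.2/NRT1.8 (AT4G21680) from 1.67 ± 0.391 to 35.2 ± 3.295 RPKM. The dual-affinity transporter and nitrate sensor NPF6.3/NRT1.1 (AT1G12110) fell from 82.2 ± 1.89 to 25.4 ± 0.616 RPKM, and the vacuolar exchanger CLCA (AT5G40890) from 51.4 ± 3.02 to 17.6 ± 0.991 RPKM. The list was not called as shifted one way against other genes (camera adjusted p = 0.645). The test does not measure changes that go both ways.

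Among the genes of ammonium transport and of glutamine and glutamate synthesis, 10 of 13 tested members rose and 3 fell (camera adjusted p = 0.0134; adjusted p = 0.515 with an estimated correlation). The cytosolic glutamine synthetase gene GLN1;4 (AT5G16570) rose from 3.88 ± 0.0575 to 94.5 ± 10.04 RPKM, or 24.4-fold, and GLN1;1 (AT5G37600) from 92.3 ± 7.92 to 678 ± 25.1 RPKM. GLN1;3 (AT3G17820) rose from 35.0 ± 0.634 to 95.6 ± 1.43 RPKM, and the ammonium transporter AMT1;1 (AT4G13510) from 82.1 ± 1.85 to 280 ± 8.83 RPKM. The 3 that fell were the plastid glutamine synthetase GLN2 (AT5G35630), from 414 ± 35.7 to 170 ± 15.5 RPKM, and the glutamate synthases GLU1 (AT5G04140), from 102 ± 10.1 to 37.6 ± 1.33 RPKM, and GLT1 (AT5G53460), from 88.8 ± 4.6 to 59.1 ± 2.73 RPKM.

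Genes of glutamate, GABA, proline and asparagine metabolism were split, with 9 of 28 tested members higher, 14 lower and 5 not passing (camera adjusted p = 0.592). With equal totals per library 11 were higher and 10 lower. Asparagine synthetase ASN2 (AT5G65010) fell from 194 ± 15.9 to 6.14 ± 0.420 RPKM, and ASN1 (AT3G47340) from 59.997 ± 21.5 to 23.6 ± 4.38 RPKM. The glutamate dehydrogenase genes GDH1 (AT5G18170) and GDH2 (AT5G07440) fell, GDH2 from 297 ± 39.8 to 89.8 ± 4.18 RPKM, whereas GDH3 (AT3G03910) rose from 0.218 ± 0.0848 to 5.38 ± 0.674 RPKM. Glutamate decarboxylase GAD1 (AT5G17330) rose from 75.5 ± 5.81 to 109 ± 6.08 RPKM. Proline dehydrogenase PRODH1 (AT3G30775) fell from 374 ± 45.4 to 204 ± 10.5 RPKM. P5CS1 (AT2G39800), of proline synthesis, was at 7.79 ± 0.501 and 8.94 ± 0.718 RPKM and did not pass (adjusted p = 0.064).

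Amino acid transporter genes rose in 15 of 21 tested cases and fell in 5 (camera adjusted p = 0.00665; adjusted p = 0.515 with an estimated correlation). LHT1 (AT5G40780), a broad-range root and leaf uptake carrier, rose from 14.7 ± 0.708 to 205 ± 8.51 RPKM, or 13.9-fold, with a log2 fold change of 3.71 ± 0.05 (SE, adjusted p = 9.2e-09). CAT1 (AT4G21120) rose 9.64-fold, UMAMIT18 (AT1G44800) 4.26-fold, AAP6 (AT5G49630) 4.03-fold and AAP1 (AT1G58360) 1.68-fold. Of 14 tested glutamate receptor-like channel genes, 7 rose and 4 fell, or 7 and 5 when adjusted over the list alone. The largest rises there were in GLR2.5 (AT5G11210), from 2.73 ± 0.263 to 23.0 ± 1.53 RPKM, and GLR1.2 (AT5G48400), from 3.42 ± 0.470 to 17.8 ± 0.943 RPKM. This list did not pass (camera adjusted p = 0.13). It passed when genes of low level were included, both in the list and among the genes compared with it (adjusted p = 0.0022).

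On the log2(RPKM + 1) scale the largest rise was in a defence gene. PR1 (AT2G14610), a marker of salicylic acid signalling, rose from 6.49 ± 4.61 to 1236 ± 196 RPKM, or 190-fold, with a log2 fold change of 7.57 ± 0.42 (SE, adjusted p = 1.7e-06). Without ammonium nitrate replicate 1 the ratio of PR1 was 302-fold. PR2 (AT3G57260), a glucanase, rose from 0.838 ± 0.297 to 114 ± 10.6 RPKM, and the transcriptional regulator SARD1 (AT1G73805) from 3.43 ± 0.187 to 57.9 ± 2.89 RPKM. All 18 tested members of the salicylic acid and systemic defence list rose, with a median log2 fold change of 3.34 (camera adjusted p = 6.4e-10; adjusted p = 0.422 with an estimated correlation). Of the 7 jasmonate-ethylene defence genes, 6 rose and ORA59, named after its values were seen, did not pass (camera adjusted p = 0.00726; adjusted p = 0.515 with an estimated correlation). The defensin PDF1.2A (AT5G44420) rose from 3.54 ± 1.64 to 108 ± 70.5 RPKM, or 30.6-fold and 19.1-fold without glutamate replicate 2, and ERF1 (AT3G23240) from 0.458 ± 0.172 to 5.37 ± 0.169 RPKM.

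Among the largest rises outside the lists were PCR1 (AT1G14880), named for cadmium resistance, from 14.9 ± 13.8 to 912 ± 56.2 RPKM (61.1-fold, and 126-fold without ammonium nitrate replicate 1), and LURP1 (AT2G14560), from 7.67 ± 4.03 to 430 ± 5.73 RPKM. An aspartyl protease gene (AT5G10760) rose 97.3-fold, an uncharacterized gene (AT1G76960) 60.8-fold, and the cytochrome P450 genes CYP716A2 (AT5G36140) and AT5G36130 rose 95.2-fold and 74.9-fold. Without ammonium nitrate replicate 1 the ratios of these P450 genes were 186-fold and 132-fold. AT2G44240 had 2 reads over the 3 ammonium nitrate libraries and 10980 over the 3 glutamate libraries. Among the largest falls outside the lists were an F-box family gene (AT1G73120), which fell 93.4-fold, a SAUR-like gene (AT2G21210), 68.8-fold, and AT1G49500, 46.3-fold. AT1G68238, AT2G26695 and AT4G29905 also fell, with log2 fold changes of -5.76, -4.74 and -4.37.

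Jasmonate and wounding genes rose in 16 of 24 tested cases and fell in 6 (camera adjusted p = 0.0216; adjusted p = 0.579 with an estimated correlation). The repressor gene JAZ1 (AT1G19180) rose from 14.9 ± 1.83 to 66.1 ± 9.35 RPKM and the synthesis gene OPR3 (AT2G06050) from 16.8 ± 0.903 to 35.1 ± 1.56 RPKM, whereas AOC1 (AT3G25760), also of jasmonate synthesis, fell from 23.5 ± 2.4 to 8.28 ± 0.684 RPKM. The call of this list was lost without ammonium nitrate replicate 2 (adjusted p = 0.0643), with equal totals per library (adjusted p = 0.0599) and among genes with a mean of at least 5 RPKM (adjusted p = 0.295).

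Senescence genes also went both ways, with 12 of 17 higher and 5 lower (camera adjusted p = 0.0214; adjusted p = 0.515 with an estimated correlation; adjusted p = 0.0613 with equal totals per library). SAG13 (AT2G29350) rose from 4.41 ± 1.57 to 212 ± 9.29 RPKM. The protease gene SAG12 (AT5G45890), a late senescence marker, had 0 reads over the ammonium nitrate libraries and 5489 reads on glutamate, at 24.1 ± 5.34 RPKM. SGR2 (AT4G11910) rose 6.76-fold and WRKY75 (AT5G13080) 3.55-fold. The members that fell were SEN1, DIN10, NYC1, NOL and SAG21, named after their values were seen, and SEN1 fell from 507 to 53.0 RPKM. The 6 autophagy genes all rose, ATG8A (AT4G21980) by 1.81-fold (camera adjusted p = 0.0323; adjusted p = 0.579 with an estimated correlation; adjusted p = 0.0591 without the genes that had multiply mapped reads).

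Oxidative and mitochondrial stress genes rose in 9 of 9 cases (camera adjusted p = 0.000717; adjusted p = 0.515 with an estimated correlation). The alternative oxidase AOX1D (AT1G32350) rose from 1.94 ± 0.771 to 56.1 ± 5.52 RPKM and the glutathione transferase GSTU4 (AT2G29460) from 16.2 ± 2.22 to 182 ± 19.6 RPKM. Of 60 class III peroxidases, 36 rose and 8 fell (camera adjusted p = 0.00228; adjusted p = 0.523 with an estimated correlation), among them PRX52 (AT5G05340), which rose from 0.442 ± 0.353 to 45.6 ± 4.98 RPKM, or 103-fold and 184-fold without ammonium nitrate replicate 3. Of 14 hypoxia genes, 9 rose and 5 did not pass (camera adjusted p = 0.00665; adjusted p = 0.579 with an estimated correlation). LBD41 (AT3G02550) rose 2.6-fold and SRO5 (AT5G62520) 3.87-fold. The fermentation gene ADH1, at 24.6 and 24.2 RPKM, was among those that did not pass and was named after its values were seen.

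Sulfur deficiency genes rose in 12 of 14 cases and fell in 2 (camera adjusted p = 0.000968; adjusted p = 0.422 with an estimated correlation). LSU2 (AT5G24660) rose from 6.27 ± 1.01 to 43.8 ± 4.42 RPKM and the APS reductase gene APR1 (AT4G04610) from 11.3 ± 1.17 to 59.5 ± 5.94 RPKM. Phosphate starvation genes rose in 15 of 20 cases and fell in 4 (camera adjusted p = 0.0134; adjusted p = 0.515 with an estimated correlation; adjusted p = 0.0502 among genes with a mean of at least 5 RPKM). The ribonuclease RNS1 (AT2G02990) rose 20.3-fold and the acid phosphatase PAP17 (AT3G17790) 4.92-fold. PHO2 (AT2G33770), a ubiquitin-conjugating enzyme that restrains phosphate uptake, rose 3.36-fold. A rise in this list is thus not in every case a rise toward phosphate uptake.

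Iron deficiency genes rose in 15 of 22 cases and fell in 6, or 16 and 6 when adjusted over the list alone (camera adjusted p = 0.0197; adjusted p = 0.579 with an estimated correlation; adjusted p = 0.0613 with equal totals per library). The coumarin synthesis genes F6'H1 (AT3G13610) and S8H (AT3G12900) rose, F6'H1 from 47.2 ± 5.47 to 162 ± 12.1 RPKM, and so did the phloem transporter OPT3 (AT4G16370), from 31.2 ± 3.79 to 119 ± 7.83 RPKM. The nicotianamine synthase NAS1 (AT5G04950) fell from 37.4 ± 4.40 to 1.07 ± 0.223 RPKM. The other members that fell, named after their values were seen, were the iron transporter IRT1, the ferric reductase FRO2, their regulator FIT, the proton pump AHA2 and CYP82C4.

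Photosynthesis genes of the nucleus fell in 27 of 37 cases and rose in 7, with a median log2 fold change of -0.71 (camera adjusted p = 0.0027; adjusted p = 0.61 with an estimated correlation). Ferredoxin FD2 (AT1G60950) fell from 1163 ± 63.7 to 256 ± 26.9 RPKM and the photosystem subunit gene PSAN (AT5G64040) from 610 ± 32.8 to 157 ± 23.9 RPKM. The Rubisco small subunit gene RBCS1B (AT5G38430) fell from 3807 ± 110 to 1261 ± 113 RPKM, with a deposited share of multiply mapped reads of 0.20. The 7 that rose, named after their values were seen, were LHCB1.1, LHCB2.1, LHCB2.2, LHCB2.3, LHCB4.2, LHCB4.3 and LHCA4, all of light-harvesting proteins. Transcripts of the chloroplast genome took 0.0392% ± 0.00302 of reads on ammonium nitrate and 0.0267% ± 0.000756 on glutamate (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 allows). Shares this small are not taken as a measure of chloroplast transcript levels.

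Markers of root cell types also differed between the groups. All 9 root hair genes rose (camera adjusted p = 0.0197; adjusted p = 0.579 with an estimated correlation), RHD6 (AT1G66470) by 3.38-fold; only 4 of them had a mean of at least 5 RPKM, where the adjusted p was 0.218. Suberin genes rose in 9 of 10 cases (camera adjusted p = 0.00485; adjusted p = 0.579 with an estimated correlation), FAR1 (AT5G22500) by 3.26-fold and CYP86A1 (AT5G58860) by 1.83-fold. Of 10 endodermis genes, 7 rose and 1 fell, and this list did not pass (camera adjusted p = 0.0812). It passed without ammonium nitrate replicate 1 (adjusted p = 0.0278) and without the filter on level (adjusted p = 0.0223). Removing the filter added no member to this list, only genes of low level to those compared with it. CASP4 (AT5G06200) rose and SCR (AT3G54220) fell, with log2 fold changes of 1.05 and -0.39. Of the 5 root tip genes 1 reached the filter, BRN1, at 1.22 and 1.57 RPKM, and it did not pass. In a second list of 16 root-expressed genes, 7 rose, 5 fell and 4 did not pass, with a median log2 fold change of 0.18. Aquaporin genes fell in 17 of 24 cases and rose in 6 (camera adjusted p = 0.0149; adjusted p = 0.579 with an estimated correlation; adjusted p = 0.0565 with genes of low level included). TIP2;2 (AT4G17340) fell from 211 ± 51.4 to 28.9 ± 1.58 RPKM, whereas NLM1 (AT4G19030) rose from 19.1 ± 2.64 to 54.9 ± 3.12 RPKM.

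**Figure D2:**
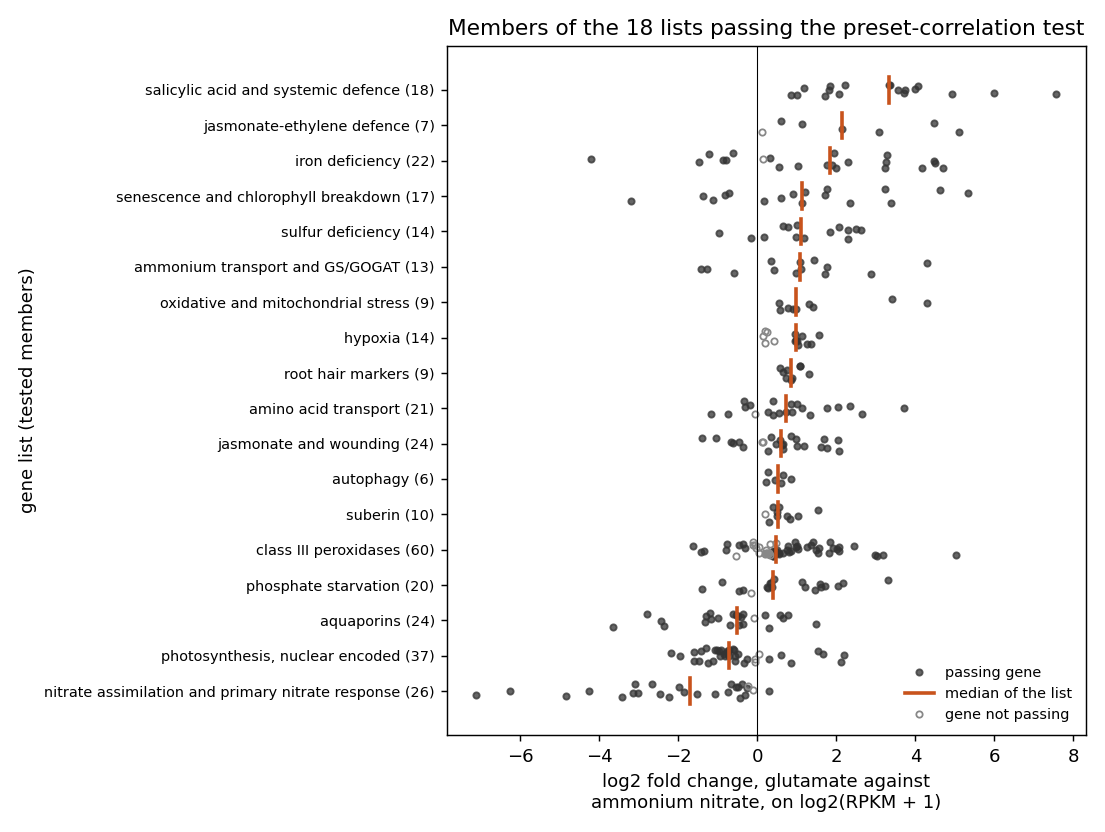
Log2 fold changes, glutamate against ammonium nitrate on log2(RPKM + 1), of the tested members of the 18 lists that passed camera with the preset correlation, one point per gene (filled, passing; open, not passing), with the list medians as orange bars. The medians run from -1.69 for nitrate assimilation to 3.34 for salicylic acid defence.

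The remaining lists did not pass. Cytokinin genes fell in 13 of 21 cases and rose in 4, or 5 when adjusted over the list alone (camera adjusted p = 0.0736; adjusted p = 0.0354 with equal totals per library and 0.0262 among genes with a mean of at least 5 RPKM). The synthesis gene IPT3 (AT3G63110) fell 5.97-fold and the response regulator ARR7 (AT1G19050) 3.59-fold. Glucosinolate genes rose in 8 of 21 cases and fell in 11, or 12 when adjusted over the list alone (adjusted p = 0.592), with MAM1 (AT5G23010) down 3.93-fold and CYP83B1 (AT4G31500) up 3.33-fold. Flavonoid and anthocyanin genes rose in 6 of 16 cases and fell in 9 (adjusted p = 0.835), and PAP2 (AT1G66390), a regulator of anthocyanin synthesis, rose from 0.266 ± 0.0648 to 27.1 ± 3.56 RPKM. Of 10 clock genes, 6 rose and 3 fell (adjusted p = 0.282; 0.0195 with genes of low level included), GI (AT1G22770) up 2.88-fold and BOA (AT5G59570) down 1.6-fold. Starch genes rose in 5 of 11 cases and fell in 3 (adjusted p = 0.648), with the glucose phosphate translocator GPT2 (AT1G61800) up from 0.232 ± 0.0840 to 24.6 ± 3.38 RPKM. Auxin genes rose in 11 of 22 cases and fell in 9 (adjusted p = 0.985), with IAA3 (AT1G04240) down and GH3.5 (AT4G27260) up, at log2 fold changes of -1.12 and 0.94. Abscisic acid genes rose in 7 of 18 cases and fell in 5 (adjusted p = 0.552), with RAB18 (AT5G66400) at -2.02 and COR15A (AT2G42540) at 1.89 on the log2 scale. Expansins rose in 11 of 22 cases and fell in 8 (adjusted p = 0.69), with EXPA17 at 2.33 and EXPA16 at -2.29. Heat shock proteins rose in 13 of 46 cases and fell in 15 (adjusted p = 0.69), and HSP17.6A (AT5G12030) rose from 2.08 to 7.72 RPKM. Of 22 cell cycle genes, 2 rose and 1 fell, or 1 and 1 when adjusted over the list alone (adjusted p = 0.779), with TSO2 (AT3G27060) at 0.70 and MCM5 (AT2G07690) at -0.35 on the log2 scale. The medians of the cell cycle, heat shock and starch lists changed sign with equal totals per library, where 17 heat shock genes rose and 13 fell. Of 5 ribosomal proteins with a 40S or 60S product name, 2 fell and 3 did not pass (adjusted p = 0.645). In the lists for which no count adjusted over the list alone is given, that adjustment gave the same counts.

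In all, 18 of 33 lists passed camera with the preset correlation, 15 higher and 3 lower. With an estimated correlation 0 passed, 2 lists had an unadjusted p under 0.05 and the lowest adjusted p was 0.422. Correlation alone does not account for the lost calls. The sulfur deficiency list had an estimated correlation of 0.0141, near the preset 0.01. Its unadjusted camera p still went from 0.000117 to 0.0197. A call lost with an estimated correlation is thus no measure of no shift. By fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, 30 lists passed. The direction given by camera differed in sign from the median for the auxin, starch and ribosomal protein lists, and from the mean for the auxin and flavonoid lists.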

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

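The tests of read sharing, of root RNA and of harvest time were chosen after the patterns were seen, and before the values that they measure were. The summed share of transcripts of the mitochondrial genome is used in no comparison of the report. These transcripts took 0.0285% ± 0.00325 of reads on glutamate and 0.0144% ± 0.00142 on ammonium nitrate (SD, n = 3), a ratio of 1.98; the level above the ammonium nitrate libraries drew attention to it (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 allows). A share this small is not taken as a measure of mitochondrial transcript levels. Groups of 3 are too small for a test of single outlying libraries.

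Of the 14 tested genes of the light-harvesting complex of photosystem II, 7 fell and 6 rose on glutamate, the 6 being LHCB1.1, LHCB2.1, LHCB2.2, LHCB2.3, LHCB4.2 and LHCB4.3. LHCB1.1 rose from 44.5 to 205 RPKM while LHCB1.3 fell from 9415 to 3403 RPKM, and these LHCB genes were named after their values were seen. Reads shared between near-identical copies are a technical explanation; the 6 genes that rose had a median deposited share of multiply mapped reads of 0.000109 and at most 0.000862, which argues against it. A real difference in the regulation of these copies by the nitrogen source stays open as a hypothesis and was not tested.

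Root hair and suberin genes rose while most of the listed photosynthesis genes fell, which may come from a larger share of root RNA in the glutamate libraries. A second list of 16 root-expressed genes had a median log2 fold change of 0.18 (95% bootstrap interval -0.47 to 0.65), with 7 higher, 5 lower and 4 not passing. ARSK1 rose from 5.44 to 15.7 RPKM and SKOR fell from 3.47 to 0.256 RPKM, both named after their values were seen. An even rise of all root genes is not seen. The interval came from resampling these genes and not the libraries, so it shows how far the genes differ. It cannot exclude a larger root share. Regulation by the nitrogen source and a change in root share cannot be told apart here.

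Of the 10 tested clock genes 6 rose, among them GI, FKF1, ELF4 and PRR7, while ELF3, LUX and BOA fell. PRR7, ELF3 and LUX were named after their values were seen. An earlier harvest of the glutamate seedlings is a candidate explanation. Genes peaking in the morning (6 tested) had a lower median than evening genes (5 tested), a difference of -0.529 with a 95% bootstrap interval of -1.39 to 0.68. The sign is opposite to an earlier harvest, but the interval spans 0. This interval also came from resampling the genes and not the libraries. Harvest time and the nitrogen source cannot be told apart with so few genes.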

How the results depend on the processing

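The voom fit and the removal of genes with multiply mapped reads were chosen after the data were seen. The count of changed genes ran from 11610 of 15539 tested with a filter at 5 RPKM to 14608 of 33602 tested without a filter. These counts thus differ in the number of genes tested. No gene called in both the main fit and an alternative changed sign. Leaving out each library in turn gave 13208 to 14005 changed genes, with 6409 to 6836 higher and 6799 to 7169 lower. It gave 2901 to 3103 genes changed at least 2-fold, with 1863 to 1976 higher and 1013 to 1161 lower, and 17 to 19 passing lists, with 14 to 16 higher and 3 lower each time. A pseudocount of 5 RPKM gave 1632 genes changed at least 2-fold, 1041 higher and 591 lower, since it shrinks log2 fold changes. A pseudocount of 0.1 RPKM gave 3699, with 2266 higher and 1433 lower, and voom 3795, with 2316 higher and 1479 lower. The test against a 1.5-fold change, which replaces the 2-fold criterion, called 2304 genes higher and 1799 lower. With an estimated correlation 0 lists passed limma's camera, 0 higher and 0 lower, with 2 lists at an unadjusted p under 0.05 and 30 lists passing fry. Equal totals per library moved the share of higher genes among those changed from 48.7% to 58.5%, with 8452 higher and 5989 lower, and the median log2 fold change of all genes from -0.02 to 0.08. The share of higher genes among those changed at least 2-fold moved from 63.2% to 72.3%. Voom on the recovered reads called 14413 genes. With the replicate number as a block, 14194 genes changed, 6929 higher and 7265 lower, and 18 lists passed. Libraries with the same number had correlations of their deviations of 0.105, 0.0481 and -0.0125. Those with different numbers had -0.179 to 0.134. No pairing by number is seen, but 3 libraries per group are too few to exclude it. Of the 158 named genes' results under the alternatives, 2651 kept their call, 6 gained one, 1 lost it and 0 reversed. The loss was CYCB1;4 without glutamate replicate 2 (0.21 on the log2 scale, limma adjusted p = 0.0567). The planned count models were not run, since the deposited unit is RPKM.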

Other observations

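The groups in this part were chosen after the data were seen. Of 24 families taken by product name, 13 passed camera with the preset correlation. The p-values are adjusted over 28 tests, which include 4 branches of the fixed lists; the branches were picked by the direction of their members, so their tests are neither counted nor given, and their genes appear further on only as values. With an estimated correlation 0 families passed after this adjustment, with 4 at an unadjusted p under 0.05. Ribosomal proteins by product name fell together on glutamate, with 232 of 281 tested genes lower and 8 higher and a median log2 fold change of -0.38 (camera adjusted p = 1.54e-13; adjusted p = 0.416 with an estimated correlation). With equal totals per library 200 of them were lower, with a median of -0.27. Of 225 pentatricopeptide repeat proteins, which process organelle RNA, 138 fell and 7 rose (adjusted p = 9.31e-08; adjusted p = 0.315 with an estimated correlation). WRKY transcription factors rose in 40 of 50 cases and fell in 5, with a median of 0.98 (adjusted p = 4.27e-08; adjusted p = 0.0542 with an estimated correlation). Adjusted over the 24 families alone, a choice made after the result was seen, the latter p was 0.0464, so this call depends on which tests are counted. NBS-LRR disease resistance genes rose in 65 of 96 cases and fell in 8 (adjusted p = 6.19e-07; adjusted p = 0.416 with an estimated correlation). SAUR genes fell in 33 of 56 cases and rose in 15 (adjusted p = 0.0277; adjusted p = 0.326 with an estimated correlation).

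The iron and glucosinolate lists held members of both directions, given here as values picked after they were seen. In the iron list the 7 genes of the bHLH Ib and IMA families rose, with a median log2 fold change of 4.17. BHLH38, a transcription factor of the iron deficiency response, rose from 2.22 to 59.6 RPKM, and IMA1, a peptide of iron signalling, from 5.11 to 101 RPKM. Among the members that fell, IRT1 went from 9.04 to 2.57 RPKM and FRO2 from 2.72 to 1.11 RPKM. In the glucosinolate list the 9 genes of the aliphatic branch fell, or 8 with equal totals per library. Of 6 genes of the indole branch 4 rose and 2 did not pass.

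Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many changed genes as the real grouping, which was the real grouping itself. The real value was 14390 changed genes by limma, and the highest of the others 0, at 43 to 170 genes with an unadjusted p under 0.05. For changes of at least 2-fold the values were 3018 and 0, and for passing lists 18 and 13, again with 1 split as high. In each of the other splits an arm held 2 libraries of one nitrogen source and 1 of the other. The contrast between the sources thus entered the spread within the arms, which by itself keeps the gene counts low. Part of the contrast also stayed between the arms. Neither the gene counts nor the lists of these splits are therefore a measure of no change. With 10 splits a share under 0.05 cannot be reached.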
